A study of Homo sapiens with 20 samples.

How the data were processed

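Messenger RNA was measured on 20 one-colour Agilent whole genome arrays, 5 for each of 4 groups of primary human fetal lung fibroblasts: a negative control precursor, the let-7d precursor, the miR-30b precursor, and both. Per the labels, 150000 cells per well were transfected at 100 nM with a cationic lipid, total RNA was taken after 24 h, and Cy3-labelled RNA was hybridized to the arrays. Whether the combined group received 100 nM of each precursor or in total was not stated.

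The deposited scanner files, 1 per array, hold a processed signal for each spot, which is an intensity after background subtraction and detrending by the software, with no scaling between arrays; the raw median signal and its local background are intensities too. The deposited value table holds log2 values of 29807 of the 41000 probes, normalized by the authors between arrays by a method that was not stated. Set against the scanner values of each array, it correlated at r = 0.995 or more, with an offset that changed with intensity, so its scale is log2, its direction is that of the signal, and its centring stayed unknown. The medians of its columns, in replicate order, were 7.29, 7.36, 7.34, 7.36, 7.30 for the control arrays, 7.30, 7.39, 7.39, 7.37, 7.34 for let-7d, 7.29, 7.39, 7.35, 7.40, 7.32 for miR-30b and 7.31, 7.39, 7.25, 7.35, 7.31 for both. Per the file headers the scans were read with a later release of Agilent Feature Extraction than version 9.5.3, which the labels name, and the grid is that of a slide with 4 arrays, where the labels name one with more.

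The main values were log2 of the processed signal minus the array's own 75th percentile, with the spots of a probe averaged. Control spots were left out, and so were spots that the software called non-uniform or outlying; 96 probes with no unmarked spot on at least 1 array were dropped. No spot was saturated. Genes of the Y chromosome and XIST, 63 probes, were left out throughout. A probe was kept when it was well above background on at least 4 of the 5 arrays of at least 1 group, which left 28804. A probe was named through its RefSeq accession, without version, in a table of current symbols: 23958 of 41000 probes received 1 symbol, 0 received several and 17042 received none, for 16557 distinct symbols. Unnamed probes were tested on their own only. Where a gene had several probes, the brightest on average stood for it, and other probes of some named genes are given where they differ; this left 12993 genes. Genome positions and untranslated sequences were not part of the reference used here, so planned counts of seed matches in untranslated regions were not run.

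Depth on these arrays is signal over background: 61.7 to 73.2% of the probes of an array were well above background, and precision is limited by the number of arrays. A gene whose probes were not well above background on any array of a group has only a bound there. It is given as "at least N-fold", from the mean normalized log2 value of the brighter group against the mean, per array, of the higher of the gene's own value and the lowest signal among probes well above background.

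Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), fitting 4 group means to all 20 arrays, so that the groups share 1 estimate of the spread. The comparisons were each treated group against control, the interaction (the combined effect minus the sum of the single effects), and the 3 comparisons between treated groups. P-values were adjusted over 12993 genes by Benjamini-Hochberg, and an adjusted p under 0.05 passed. The slide, which holds 1 array of each group and has the replicate number, was fitted as a block for the values given with it. Slide and scan coincide, and position on the slide coincides with group.

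In all, 27 gene lists were fixed before the data were examined: let-7 targets, miR-30 targets, collagens, other extracellular matrix, matrix modifying enzymes, contractile myofibroblast genes, mesenchymal transition factors, the TGF-beta and BMP pathway, G1/S and DNA replication, G2/M and mitosis, p53 targets, interferon response, inflammatory cytokines and chemokines, the small RNA pathway, autophagy, endoplasmic reticulum and amino acid stress, cholesterol synthesis, hypoxia and glycolysis, RAS and growth factor feedback, cytosolic ribosomal proteins, the respiratory chain, and epithelial, endothelial, leukocyte, pericyte and smooth muscle, mesothelial and erythroid markers. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

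The genes named were chosen by a rule fixed before the data were examined. For each comparison with control it took the 10 largest rises and 10 largest falls among genes that passed and whose 5 treated values all lay beyond the 5 control values, and for the other comparisons the 5 largest each way. From each list it took up to 4 members with the lowest p, and it added known targets and fibrosis genes, among them HMGA2, LIN28B, IGF2BP1, IGF2BP2, IGF2BP3, DICER1, NRAS, CDC25A, CDK6, TWF1, GALNT7, SNAI1, NT5E, PPP3R1, COL1A1, COL3A1, ACTA2, FN1 and CCN2. INHBA and ATG12, each the single member of a list that rose, and any other name outside this rule were chosen after their values were seen. Some genes that the rule selected are not reported here, though the counts include them.

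The single effects were compared across genes by Pearson correlation, covariance and overlap of calls. Unchanged groups were simulated 100 times against the same controls, and the controls were split between the comparisons in 20 ways.

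The alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, median scaling, the deposited value table, no filter on dim probes, a filter asking for all 20 arrays, the mean of a gene's probes, eBayes with trend and robust, a minimum change of 1.5-fold, a fit of only the groups compared, the slide or replicate number as a block, the set tests named above, and leaving out each array in turn. Normexp used the median signal in place of the mean signal, which the scanner files do not hold. Alternatives added after seeing the data were array brightness as a covariate, with and without the block, leaving out the low region of 1 array, every probe on its own, and leaving out the dimmest array and the array with the low region. The procedure was tested on simulated data: with changes of 1.5-, 2- and 4-fold placed in simulated arrays with each gene's mean and spread, 34.3%, 64.2% and 93.9% of the changed genes passed in the comparison of let-7d with control and 3 of the unchanged genes did, against 4 for miR-30b, 15 for both and 6 for the interaction, and a raised list was found with 0 false lists. The simulated noise was independent between genes and arrays, and the simulated lists were random. The false calls and false lists to expect with slide effects, differences in brightness or correlated genes are therefore not covered. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.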

Results

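The series measured messenger RNA in primary human fetal lung fibroblasts, the connective tissue cells of the lung, 24 h after transfection with small RNA precursors at 100 nM. One group of 5 arrays received the let-7d precursor, one of 5 the miR-30b precursor, one of 5 both precursors and one of 5 a negative control precursor. Both molecules are microRNAs, short RNAs that lower the level or translation of messenger RNAs carrying matching sites. The series title names them as microRNAs reduced in idiopathic pulmonary fibrosis, so the design asks what a higher dose of each, alone or combined, does to the fibroblast transcriptome. The labels do not state whether the combined group received 100 nM of each precursor or in total.

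Each of the 20 one-colour arrays carried 45015 spots, and 61.7 to 73.2% of the probes were well above background. The filter on dim probes left 28804 probes, and 12993 named genes were tested in each comparison. All values below are log2 fold changes with the standard error of the limma fit (SE) over 5 arrays per group. It depends on the number of arrays and on the spread of the gene between arrays. Arrays of 1 group correlated at r = 0.930 or more across genes, which are not independent replicates. The control arrays, whose cells were transfected too, were brighter on average than those of the other groups. The log2 75th percentile of their signal was 10.06 ± 0.30 (SD, n = 5), against 9.28 ± 0.94 with let-7d, 9.07 ± 0.52 with miR-30b and 9.18 ± 0.78 with both. Two-sided exact permutation p was 0.0556, 0.0159 and 0.0556, each with a Benjamini-Hochberg value of 0.0952 over 12 such comparisons. Each slide held 1 array of every group, and the position on the slide was the same for all arrays of a group, so position and group cannot be told apart. On 1 array of the combined group, replicate 3, a round region with 3.68% of the gene spots read low; values without it are given where a named gene lay there.

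**Figure D1:**
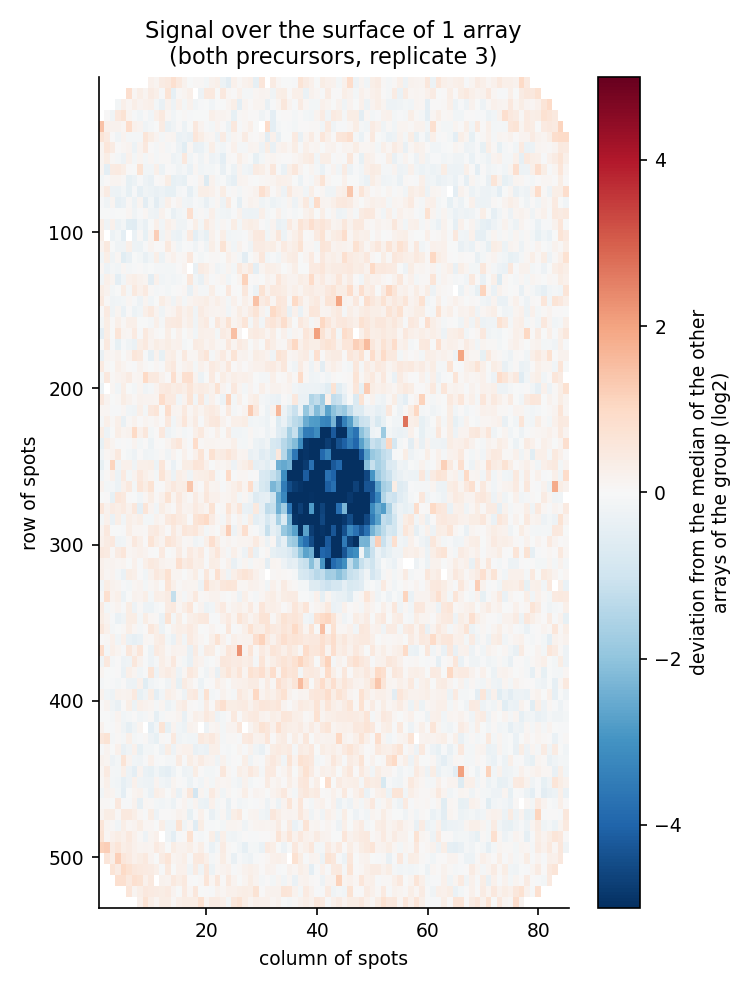
Deviation of the signal on replicate 3 of the combined group from the median of that group's other arrays (log2, median of neighbouring spots, colours limited to -5 and 5), drawn at the column and row of the spots on the array. The round low region spans rows 211 to 320 and columns 32 to 53, with a median deviation of -3.96.

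let-7d lowered a set of known let-7 targets, led by HMGA2, a chromatin protein of growing and embryonic cells, which was 4.35-fold lower (-2.12 ± 0.11, adjusted p = 1.05e-09). DICER1, the enzyme that cuts microRNA precursors, fell by 1.07 on the log2 scale, and the RNA-binding proteins IGF2BP1 and IGF2BP2 fell by 1.20 and 1.11. In the other direction, genes for inflammatory cytokines and chemokines rose together, with CSF2, the granulocyte-macrophage colony-stimulating factor, at least 7.77-fold higher. Several ligands and regulators of TGF-beta and BMP signalling, among them SMAD6, TGFB3 and BMP4, were lower. In all, 2101 of 12993 genes changed, 1047 higher and 1054 lower, and 3182 with the slide as a block.

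Of the 37 measured members of the let-7 target list, 18 fell, 1 rose and 18 did not pass the test. Adjusted over the list alone, 25 were lower and 3 higher. The list as a whole lay below the other genes (mean -0.61, camera adjusted p = 2.07e-10; adjusted p = 0.000148 with an estimated correlation and 1.57e-09 with the slide as a block), and its mean was negative on 5 of 5 slides (-0.70 to -0.55). RDH10, a retinol dehydrogenase, fell by 1.93, the carboxypeptidase CPA4 by 1.76, and the GTPase gene NRAS by 0.96. CDC25A (-0.44 ± 0.16, adjusted p = 0.0685) and IGF2BP3 (0.02 ± 0.20, 0.958) did not pass, though a dimmer second probe of CDC25A lay at -1.27. A dimmer second probe of HMGA2 lay at 0.28 and one of IGF2BP1 at -0.34, while second probes of DICER1, IGF2BP2, RDH10 and CPA4 lay at -1.18, -1.51, -1.26 and -1.92. LIN28B, another known let-7 target, did not pass the filter on dim probes.

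**Figure D2:**
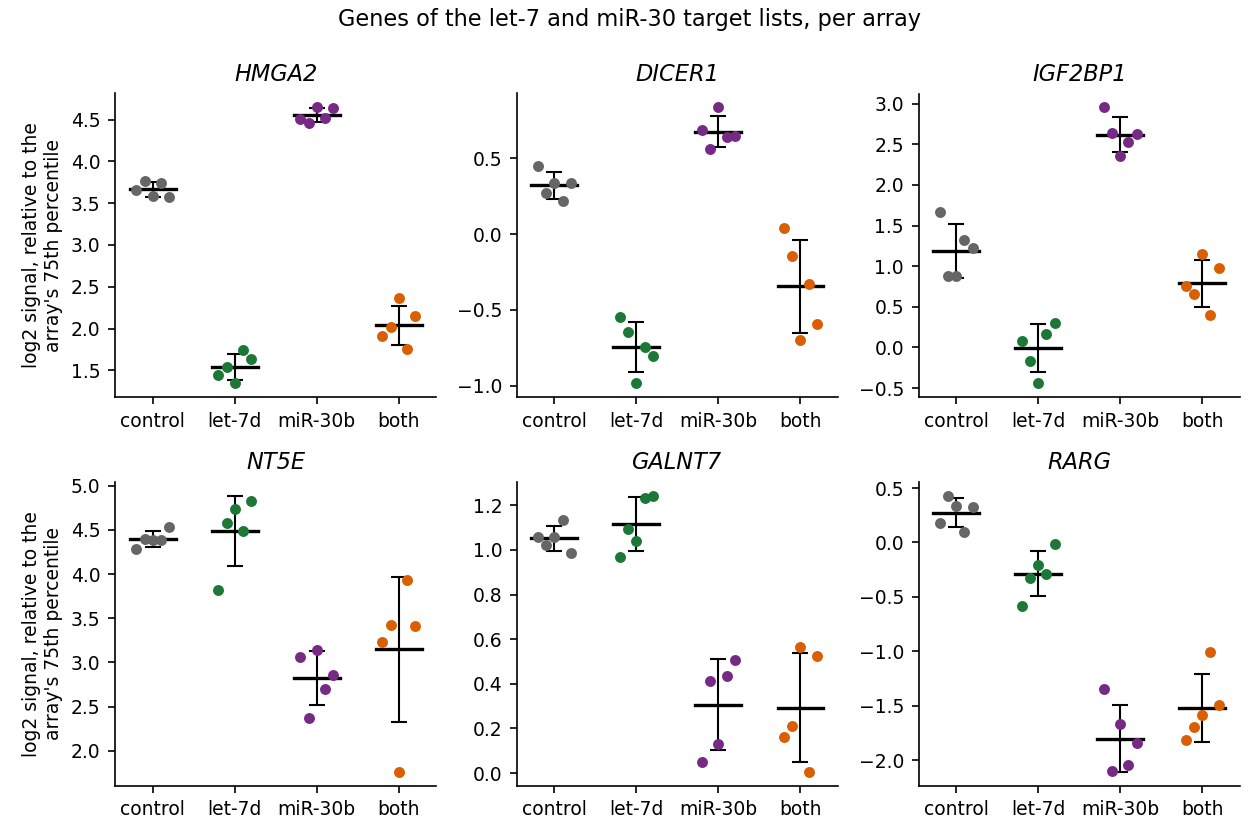
Normalized log2 signal of 6 genes in the 4 groups, all but RARG from the let-7 and miR-30 target lists. RARG is in neither list, though the title inside the figure names them. Each point is 1 array, the thick bar is the group mean and the error bar the SD (n = 5). HMGA2 and DICER1 were lower with let-7d (-2.12 and -1.07) and with both precursors (-1.63 and -0.67), NT5E, GALNT7 and RARG with miR-30b (-1.57, -0.74 and -2.08) and with both, and IGF2BP1 moved down with let-7d (-1.20) and up with miR-30b (1.43).

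The cytokine and chemokine list rose with let-7d: 12 of 24 measured members were higher, 0 were lower and 12 did not pass (14 higher when adjusted over the list alone). Its mean was 0.73 (camera adjusted p = 2.85e-05; adjusted p = 0.00103 with an estimated correlation), positive on 5 of 5 slides (0.68 to 0.82; 0.000112 with the slide as a block). The neutrophil attractant CXCL1 rose by 1.43, the monocyte attractant CCL2 by 1.76, IL1B by 1.64 and LIF by 1.35. Leukocyte markers rose as well (3 of 10 higher, mean 0.75, camera adjusted p = 0.0433; adjusted p = 0.463 with an estimated correlation and 0.0259 with the slide as a block; slide means 0.14 to 1.48), namely CD79A (1.92), TYROBP (1.33) and CSF1R (0.70); CD79A belongs to the co-varying set described below. So did erythroid markers (2 of 7, mean 0.86, 0.0433; adjusted p = 0.45 with an estimated correlation and 0.0259 with the slide as a block; slide means 0.57 to 1.26) and endothelial markers (2 of 8, mean 0.49, 0.0454; adjusted p = 0.45 with an estimated correlation and 0.0259 with the slide as a block; slide means 0.34 to 0.93). With array brightness as a covariate the cytokine list still passed (adjusted p = 5.58e-08), and the leukocyte, erythroid and endothelial lists did not (0.107, 0.0987 and 0.0847). Without the dimmest array and the array with the low region the 3 marker lists did not pass either (0.0607, 0.0553 and 0.0804).

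Of 30 measured genes of the TGF-beta and BMP pathway, 7 fell, 1 rose and 22 did not pass (10 lower and 1 higher over the list alone). The mean was -0.31 (camera adjusted p = 0.00116; adjusted p = 0.325 with an estimated correlation), negative on 5 of 5 slides (-0.65 to -0.10; 0.00262 with the slide as a block). SMAD6, an inhibitor of BMP signalling, fell by 1.21, the ligands TGFB3 and BMP4 by 0.94 and 0.92, and ID2, a target of BMP signalling, by 0.45, while INHBA, an activin subunit, rose by 0.67. Collagens were lower as a list (5 of 21 fell, mean -0.15, camera adjusted p = 0.0454; adjusted p = 0.45 with an estimated correlation and 0.0508 with the slide as a block; slide means -0.21 to -0.11). COL3A1 fell by 0.64 (adjusted p = 0.0323), and COL5A1 by 0.68; other probes of COL3A1 lay at -1.04 and -0.96. The call of COL3A1 ended with array brightness as a covariate (-0.37, adjusted p = 0.106) and without any 1 of control replicates 1, 2, 3 and 5 and let-7d replicates 1, 2 and 4 (adjusted p from 0.0522 to 0.0862). COL1A1 had no named probe. Other matrix genes gave 4 lower and 1 higher of 31 (mean -0.09, camera adjusted p = 0.0434; adjusted p = 0.45 with an estimated correlation and 0.0508 with the slide as a block; slide means -0.25 to -0.01). THBS1 and NID2 fell by 0.91 and 1.00, TNXB, of the same co-varying set, rose by 2.88, and FN1, fibronectin, did not pass (-0.28 ± 0.14; other probes at 0.19 and -0.58). ACTA2, the smooth muscle actin of myofibroblasts, fell by 0.46 (adjusted p = 0.00514) within a contractile list that did not pass (4 lower and 0 higher of 21, adjusted p = 0.127).

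Genes of the small RNA pathway were lower as a list (6 lower, 1 higher of 17, mean -0.20, camera adjusted p = 0.0454; adjusted p = 0.271 with an estimated correlation and 0.0508 with the slide as a block; slide means -0.26 to -0.12). They included TNRC6C (-1.40), a scaffold of the silencing complex, MOV10 (-0.83), an RNA helicase that binds it, the Argonaute gene AGO1 (-0.41) and DICER1, which also stands in the let-7 target list. RAS and growth factor feedback genes were higher as a list (6 higher, 1 lower of 26, mean 0.18, adjusted p = 0.0483; adjusted p = 0.45 with an estimated correlation and 0.0966 with the slide as a block; slide means -0.12 to 0.34), with DUSP6, a phosphatase of the ERK kinases, at 0.86 and the growth factor AREG at 0.97. Respiratory chain genes were higher (4 of 34, mean 0.29, adjusted p = 0.0203; adjusted p = 0.517 with an estimated correlation, 0.0259 with the slide as a block, slide means 0.23 to 0.33, and 0.128 with quantile normalization), NDUFA6 and COX6C by 1.01 and 0.67. Cytosolic ribosomal proteins had a mean of 0.37 (adjusted p = 0.00106; adjusted p = 0.537 with an estimated correlation and 0.000273 with the slide as a block; slide means 0.20 to 0.67), but -0.16 with quantile normalization, so their direction depended on the scaling; 1 of 38 members, RPS3, passed alone.

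The largest changes against control named below are those of genes that passed and whose 5 treated values all lay beyond the 5 control values, so a larger mean with overlapping groups is not ranked; the order is that of the fitted difference, also where only a bound is given. The 10 largest rises with let-7d were SOX8 (4.84), NEUROG1 (4.83), CEBPA (4.34), FOXB1, CSF2, GPR78, KISS1R, GRIN1, ASCL2 and TSPAN10 (3.28); ASCL2, like CSF2, was not above background in the control arrays and was at least 7.05-fold higher (adjusted p = 0.0502 with normexp). Other probes of SOX8, TSPAN10 and GRIN1 lay at 0.49, 0.75 and 2.34. SOX8, NEUROG1, CEBPA and FOXB1 encode transcription factors of other lineages. Of these, 8, without CSF2 and ASCL2, belonged to a set of 192 genes that varied together between arrays of 1 group, and other probes of that set's genes had a lower median (0.20 against 2.07 for the probes used). The largest falls were EOGT, HMGA2, RTL3, RDH10, PUDP, CPA4, SFXN2, TOX, SNAP23 and SLC6A9, from -2.12 to -1.66. The share of higher genes among those changed was 49.8%, and 39.1% with quantile normalization, 39.8% with median scaling and 35.3% with normexp. Leaving out control replicate 3 or 5 brought the count to 1270 or 1282.

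**Figure D3:**
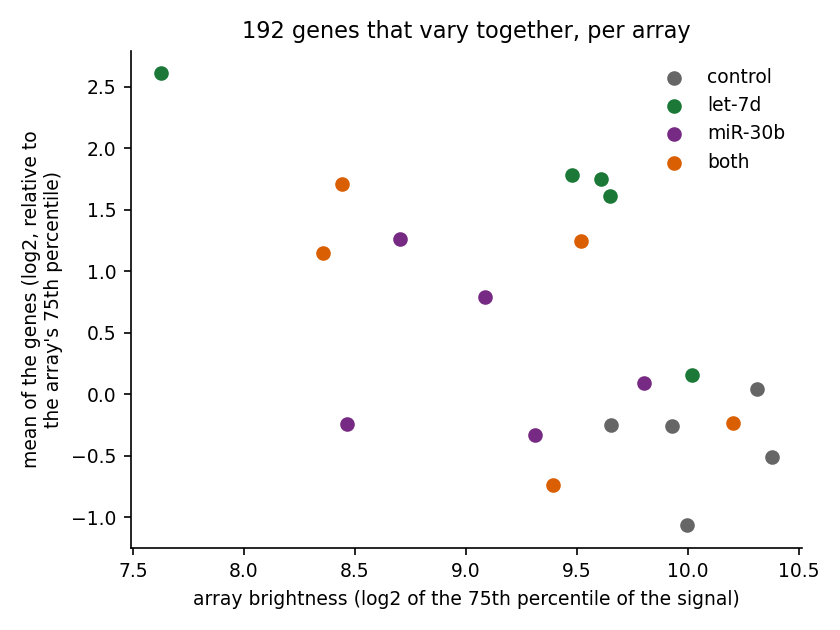
Mean normalized log2 signal of the 192 co-varying genes on each of the 20 arrays (vertical) against the log2 75th percentile of the array's signal (horizontal), coloured by group; each point is 1 array. The let-7d arrays ranged from 0.16 to 2.61, the highest on the dimmest array, and the control arrays from -1.06 to 0.04.

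**Figure D4:**
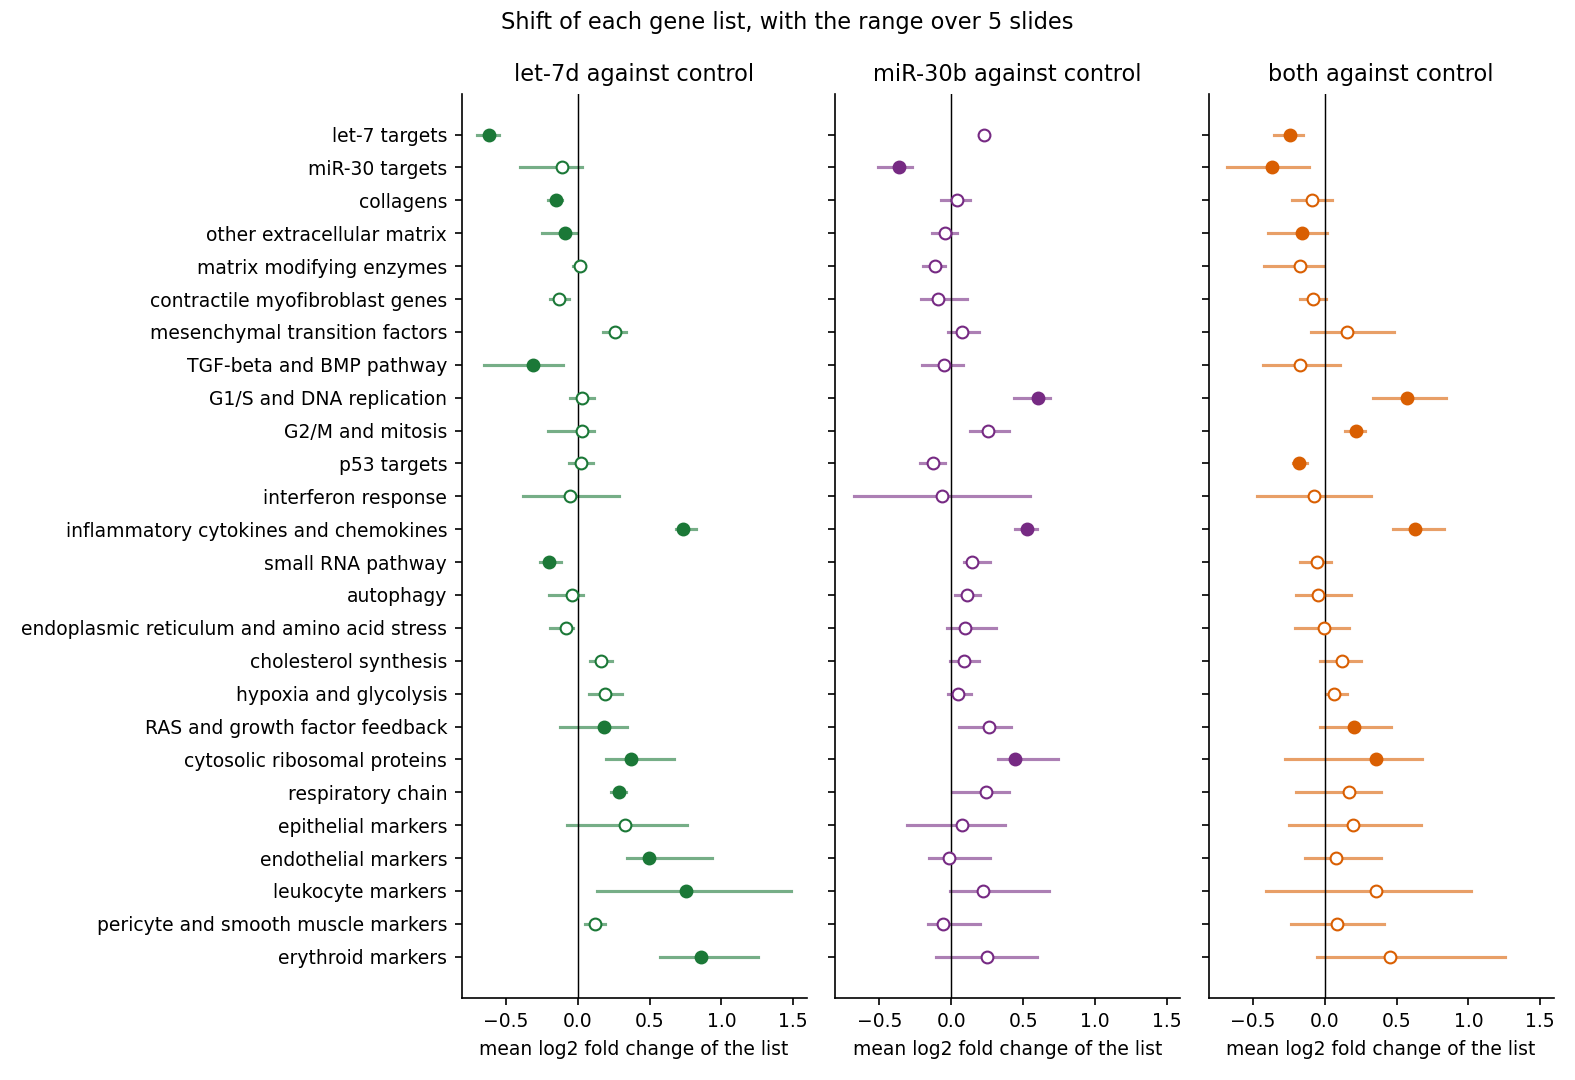
Mean log2 fold change of each gene list with at least 5 measured members in the 3 comparisons against control; filled points passed camera at an adjusted p under 0.05, and lines span the lowest to highest of the 5 within-slide means. let-7 targets lay at -0.61 with let-7d, G1/S and DNA replication genes at 0.60 with miR-30b and 0.57 with both, and cytokines at 0.73, 0.52 and 0.63; the sign of the ribosomal protein list turned with quantile normalization.

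With miR-30b, genes of the G1/S transition and DNA replication lay higher and known miR-30 targets lower than the other genes. Both lists passed at the preset correlation of camera, but neither passed with an estimated correlation (adjusted p = 0.0854 and 0.102). The miR-30 targets also did not pass with array brightness as a covariate (camera adjusted p = 0.0527). The cell cycle transcription factors E2F8 and E2F2 were 4.53-fold and 3.88-fold higher (2.18 ± 0.27 and 1.96 ± 0.25), and the kinase gene CDK6 rose by 1.44; dimmer second probes of E2F2 and CDK6 lay at 0.73 and -0.04. NT5E, the cell surface enzyme that makes adenosine, was 2.97-fold lower (-1.57 ± 0.29, adjusted p = 0.000872) and the retinoic acid receptor RARG 4.22-fold lower (-2.08 ± 0.16). In all, 3383 of 12993 genes changed, 1917 higher and 1466 lower (4180 with the slide as a block), more than in the other comparisons of a treated group with control.

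Of 39 measured G1/S and DNA replication genes, 26 rose, 0 fell and 13 did not pass, with 26 higher and 0 lower over the list alone. The mean was 0.60 (camera adjusted p = 5.92e-09; adjusted p = 0.0854 with an estimated correlation, so the call ended there), positive on 5 of 5 slides (0.44 to 0.69; 1.79e-08 with the slide as a block). CHAF1B, a chromatin assembly factor, rose by 1.14, TYMS, the thymidylate synthase, by 0.88 and the replication licensing factor CDC6 by 0.88. The list shares CDC25A (0.94, second probe 0.47), E2F2 and RRM2 (-0.58, not passing) with the let-7 targets. Genes of G2/M and mitosis did not pass as a list (12 higher and 3 lower of 38, mean 0.26, adjusted p = 0.113), although SPC25, a kinetochore gene, and CDK1, the mitotic kinase, rose by 1.36 and 0.91 and FOXM1 fell by 0.65.

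Among 37 measured miR-30 targets, 14 fell, 1, ATG12, rose and 22 did not pass (16 lower and 2 higher over the list alone). The list mean was -0.36 (camera adjusted p = 0.000655; adjusted p = 0.102 with an estimated correlation), negative on 5 of 5 slides (-0.51 to -0.27; 0.000684 with the slide as a block). With array brightness as a covariate its mean was -0.20 (adjusted p = 0.0527). The G protein subunit GNAI2 fell by 1.46, TNRC6A, a scaffold of the silencing complex, by 0.87, and GALNT7, an enzyme that starts O-linked sugar chains, by 0.74. SNAI1 (0.18 ± 0.17) and PPP3R1 (-0.20 ± 0.26) did not pass, and TWF1 fell by 0.57, a call that ended with array brightness as a covariate (adjusted p = 0.232) and without any 1 of the control replicates or miR-30b replicates 1, 2 and 4 (0.0551 to 0.0942); its second probe lay at -1.32. CCN2, of the same list and in the low region, lay at 0.81 and did not pass (adjusted p = 0.627). With the low region left out it passed as a rise (adjusted p = 0.00882). Other probes of NT5E lay at -1.13 and -0.30. The other probe of RARG, which is not in the list, lay at -1.57.

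Cytokine and chemokine genes rose with miR-30b too: 10 of 24 were higher, 0 lower and 14 did not pass (12 over the list alone; mean 0.52, camera adjusted p = 0.00174; adjusted p = 0.0245 with an estimated correlation and 0.000684 with the slide as a block), positive on 5 of 5 slides (0.44 to 0.59). CXCL1 rose by 1.73, CCL2 by 1.53, CCL7 by 1.13 and IL6 by 0.76. Leukocyte markers did not pass (1 higher and 1 lower of 10, adjusted p = 0.964). Cytosolic ribosomal proteins had 11 members higher and 1 lower of 38 (mean 0.44, adjusted p = 0.000766; adjusted p = 0.988 with an estimated correlation and 0.000219 with the slide as a block; slide means 0.33 to 0.74), and a mean of -0.04 with quantile normalization. let-7 targets did not pass as a list (12 higher and 1 lower of 37, mean 0.23, adjusted p = 0.21), although IGF2BP1, IGF2BP3 and HMGA2 rose by 1.43, 1.16 and 0.89 (second probes of IGF2BP1 and HMGA2 at -0.17 and 0.08). Matrix lists did not pass with miR-30b: collagens gave 3 higher and 1 lower of 21 (adjusted p = 0.964), other matrix genes 2 and 5 of 31 (0.679), with HAS2, a hyaluronan synthase, at -0.74 and MFAP4 at 0.89, and the TGF-beta and BMP pathway 4 and 3 of 30 (0.815).

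The largest rises with miR-30b were PKIA, RP2, FRRS1L, BTG3, E2F8, EGR2, ASB16, E2F2, PODXL and ASPH, from 2.80 to 1.92. The call of RP2 ended without any 1 of control replicates 1, 2, 3 and 5 and miR-30b replicates 2, 4 and 5 (adjusted p from 0.0639 to 0.0778), but its adjusted p was 1.58e-06 with the low region left out. BTG3, an antiproliferative gene, rose by 2.20 and PODXL, a cell surface sialomucin, by 1.95; FRRS1L was not above background in the control arrays and was at least 2.63-fold higher (adjusted p = 0.0315, and 0.257 with array brightness as a covariate). FRRS1L belongs to the co-varying set, and its call ended also with normexp (0.176) and without any 1 of control replicates 3 and 5 and miR-30b replicates 2 and 4 (0.0742 to 0.0956). The probes of ASPH differed (1.92, 0.52 and -0.39), as did those of RP2 (2.39 and 0.29) and ASB16 (2.02 and 0.20). The call of ASB16 ended with the slide and brightness fitted together (0.56, adjusted p = 0.218), and so did that of BCO2 (0.107). The largest falls were RARG (-2.08), DSG2, NECAP1, ZNF280A, GALNT15 and NT5E (-1.57). FLVCR2, BCO2, GDAP1 and MCHR1 were also selected by the fitted difference, but they were not above background with miR-30b, so their ranks are open and they were at least 2.64-fold, 1.03-fold, 1.35-fold and 1.59-fold lower. A second probe of NECAP1 lay at -0.67, against -1.64, and the call of ZNF280A ended with normexp (adjusted p = 0.128). Fitting the 2 groups alone gave 5242 changed genes.

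With both precursors, let-7 and miR-30 targets lay lower and G1/S and cytokine genes higher than the other genes. The miR-30 targets did not pass with an estimated correlation (adjusted p = 0.0943), and neither target list passed with array brightness as a covariate (0.0848 for each). RARG was 3.46-fold lower (-1.79 ± 0.16) and HMGA2 3.09-fold lower (-1.63 ± 0.11), though the second probe of HMGA2 described above lay at 0.22. G1/S genes such as E2F8 (1.66 ± 0.27) and cytokine genes such as CXCL1 (1.72 ± 0.28) were higher. Of 12993 genes, 2154 changed, 1178 higher and 976 lower, and 2869 with the slide as a block. The count rested on single arrays: it was 4226 without replicate 4 of this group, 1294 without replicate 3, and 1301, 1319 and 1391 without control replicates 3, 2 and 5.

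G1/S and DNA replication genes rose in 24 of 39 cases, 0 fell and 15 did not pass (30 higher and 1 lower over the list alone; mean 0.57, camera adjusted p = 6.42e-11; adjusted p = 0.0381 with an estimated correlation), with a positive mean on 5 of 5 slides (0.34 to 0.84; 3.25e-10 with the slide as a block). CDC6 rose by 1.23, TYMS by 0.66 and CHAF1A by 0.68. G2/M and mitosis genes passed as a list (12 higher and 2 lower of 38, mean 0.22, adjusted p = 0.0285; adjusted p = 0.5 with an estimated correlation, 0.0478 with the slide as a block and 0.0583 with quantile normalization; slide means 0.14 to 0.28), with CDK1, in the low region, at 0.85 (0.81 without it) and SPC25 at 1.31. p53 targets were lower (5 of 23 fell and 0 rose, mean -0.18, adjusted p = 0.0174; adjusted p = 0.0381 with an estimated correlation), negative on 5 of 5 slides (-0.22 to -0.12; 0.0174 with the slide as a block). Among them CDKN1A, the cell cycle inhibitor p21, fell by 0.63 and BTG2 by 0.97.

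Of 37 let-7 targets, 10 fell and 5 rose (16 and 7 over the list alone; mean -0.25, adjusted p = 0.00543; adjusted p = 0.0381 with an estimated correlation). CPA4, PLAGL2 and DICER1 fell by 1.37, 0.91 and 0.67, whereas CDK6 and E2F2 rose by 1.17 and 1.15 (second probes at 0.66 and 0.56) and IGF2BP1 did not pass (-0.40 ± 0.18). Of 37 miR-30 targets, 9 fell and 1 rose (10 and 1 over the list alone; mean -0.37, adjusted p = 0.00114; adjusted p = 0.0943 with an estimated correlation). SOCS1, a brake on cytokine signalling, fell by 1.23, NT5E by 1.25 and GNAI2 by 1.12; other probes of NT5E lay at -0.78 and -0.15, and its call ended with the slide and brightness fitted together (-0.52, adjusted p = 0.111). Both target lists had a negative mean on 5 of 5 slides (-0.35 to -0.16 and -0.68 to -0.11) and passed with the slide as a block (0.00626 and 0.00142); with array brightness as a covariate their means were -0.21 and -0.23, each with an adjusted p of 0.0848.

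Cytokine genes rose with both precursors (10 higher, 0 lower and 14 not passing of 24, 13 over the list alone; mean 0.63, adjusted p = 6.7e-05; adjusted p = 0.00304 with an estimated correlation and 3.01e-05 with the slide as a block), positive on 5 of 5 slides (0.47 to 0.83). CSF2 was at least 3.11-fold higher, CCL2 rose by 1.74 (1.65 without the low region) and PTX3, a secreted pattern recognition protein, by 0.61. Leukocyte markers did not pass (0 of 10 higher, 0.393). RAS and growth factor feedback genes were higher (7 of 26, mean 0.21, adjusted p = 0.0333; adjusted p = 0.517 with an estimated correlation and 0.0566 with the slide as a block; slide means -0.03 to 0.46), among them EGR2 (1.55) and AREG (1.18). Matrix genes other than collagens were lower (2 of 31, NID2 and THBS2, mean -0.16, adjusted p = 0.042; adjusted p = 0.531 with an estimated correlation, 0.0493 with the slide as a block and 0.381 with array brightness as a covariate; slide means -0.40 to 0.02). Collagens did not pass (2 lower of 21, adjusted p = 0.158), nor did COL3A1 (-0.57 ± 0.20, 0.0514), and ACTA2 fell by 0.36 (adjusted p = 0.023; 0.0643 without replicate 2 of this group and 0.0711 without control replicate 5, 0.063 with median scaling and 0.0628 when the compared groups were fitted alone). TGF-beta and BMP genes did not pass as a list (7 lower and 1 higher of 30, mean -0.17, adjusted p = 0.0751). CCN2, a matrix protein induced by TGF-beta, lay in the low region and did not pass (-1.29 ± 1.11; 0.40 without it, adjusted p = 0.213). Ribosomal proteins had a mean of 0.36 (adjusted p = 0.000668; adjusted p = 0.689 with an estimated correlation and 9.72e-05 with the slide as a block; slide means -0.28 to 0.68), and -0.12 with quantile normalization.

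The largest rises with both precursors were CSF2, ESM1 (2.35), PODXL (2.17), CCL13, MYB (2.06), ANGPTL4 (2.00), BTG3, PAQR9, ZNF367 and ASPH. PKIA and RP2 lay in the low region of replicate 3 of this group, so whether they belong in this ranking is open. Their normalized log2 signal was -2.41 and -3.75 there, against 1.96 to 2.99 and 1.63 to 2.70 on the other arrays of the group. CCL13 was not above background in the control arrays and was at least 2.47-fold higher, a second probe of ESM1 lay at 0.80, and others of ASPH at 0.92 and -0.13, against 1.90. The largest falls were FLVCR2 (-2.67), RARG, PUDP, HTR2B, GALNT15, HMGA2, DSG2, LMO3, VAMP3 and TLR6 (-1.48). LMO3 was not above background with both and lay close to it in the controls, so no fold is given for it, and its call ended with normexp (adjusted p = 0.0723). PUDP and HTR2B lay in the low region, and without it they changed by -1.16 and -1.14 in place of -1.75 and -1.74. The calls of PUDP, HTR2B and TLR6 ended with the slide and brightness fitted together (adjusted p = 0.116, 0.0853 and 0.134), and those of PUDP and HTR2B when the compared groups were fitted alone (0.0527 and 0.0612).

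**Figure D5:**
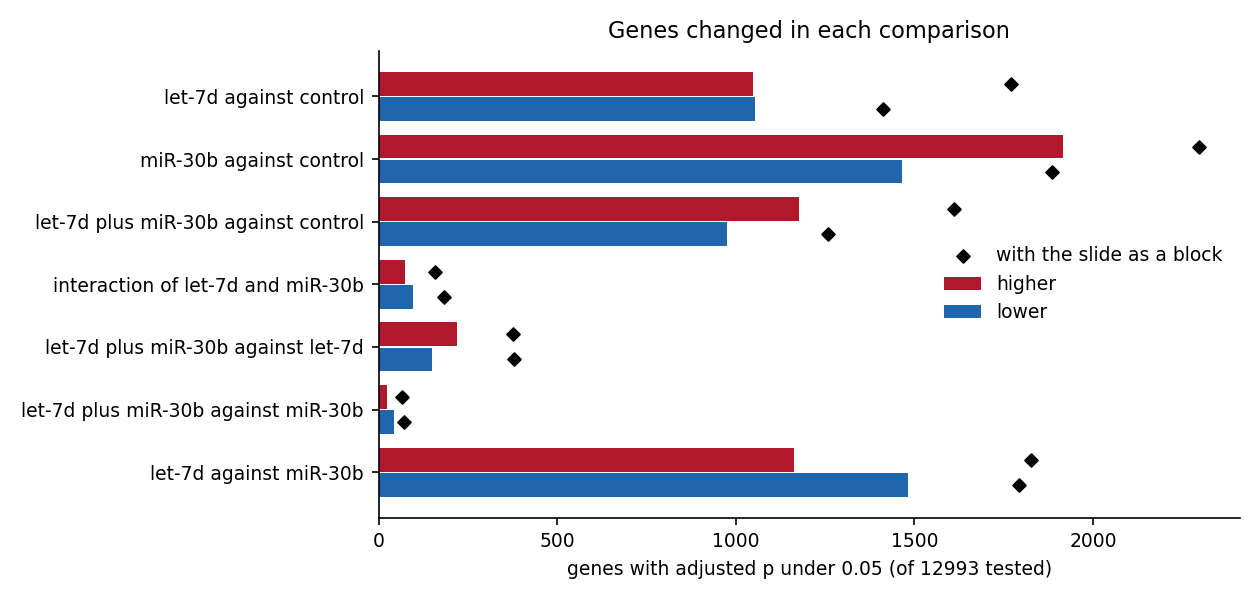
Number of genes higher (red bars) and lower (blue bars) at an adjusted p under 0.05 in each comparison, of 12993 tested; diamonds give the counts with the slide as a block. The comparisons with control gave 2101, 3383 and 2154 genes, and the interaction gave 170.

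The interaction asks whether the combined effect differs from the sum of the single effects. The labels leave open whether each precursor had a lower dose in the combined group than alone, in which case a combined effect below the sum needs no interaction. For cytokine and chemokine genes the combined effect differed from the sum: their combined rise was smaller than the sum (mean of the interaction -0.63, camera adjusted p = 1.38e-05; adjusted p = 0.00111 with an estimated correlation and 1.77e-05 with the slide as a block), negative on 5 of 5 slides (-0.78 to -0.47). CCL2 (-1.54 ± 0.29, and -1.63 without the low region, where it lay), IL1B (-1.25 ± 0.24) and LIF passed alone, 3 of 24, and 12 were lower when adjusted over the list alone. The list rose to a like extent with let-7d, miR-30b and both. A shift of the control arrays alone would give such a pattern too, and it cannot be told apart here, since position on the slide coincides with group. Ribosomal proteins passed as a list with no member passing (-0.45, adjusted p = 0.000424; adjusted p = 0.752 with an estimated correlation and 7e-05 with the slide as a block; slide means -0.95 to -0.01), and had a mean of 0.08 with quantile normalization. let-7 targets (0.14, adjusted p = 0.196), miR-30 targets (0.10, 0.168) and G1/S genes (-0.06, 0.83) did not pass, though RDH10 (1.34 ± 0.30) and CPA4 (1.26 ± 0.23) of the let-7 targets did.

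Across all genes, 170 passed the interaction test, 73 higher and 97 lower than the sum of the single effects, and 341 with the slide as a block. The largest positive values were those of the glycine transporter SLC6A9 (1.83 ± 0.39), ARHGEF35 (1.47 ± 0.31), RDH10, the splicing regulator RBFOX2 (1.30 ± 0.26) and the dynein gene DNAH5 (1.28 ± 0.31). ARHGEF35 lay in the low region, and its value without it was 1.63. The call of DNAH5 ended with the slide as a block (adjusted p = 0.0531), quantile normalization (0.0607), the deposited table (0.0619), the mean of its probes (0.395) and other settings, and its second probe lay at 0.29. The largest negative ones were CEBPA (-3.85 ± 0.94), TAF5L (-3.77 ± 0.45), PRM3 (-3.13 ± 0.67), POU3F3 (-2.84 ± 0.67) and NEUROG3 (-2.82 ± 0.61); a second probe of TAF5L lay at 1.00, and its call ended with the mean of probes (adjusted p = 0.057). CEBPA and NEUROG3 belong to the set of 192 co-varying genes described above. With median scaling the calls of SLC6A9, RDH10, CEBPA and POU3F3 ended (0.05, 0.0511, 0.0562 and 0.0511), and with normexp that of ARHGEF35 (0.0825); those of PRM3, SLC6A9 and ARHGEF35 ended with the slide and brightness fitted together (0.0702, 0.0641 and 0.0509), and that of CEBPA with brightness alone (0.0586). The count was 51 with median scaling, 42 without control replicate 2 and 359 without replicate 3 of the combined group. Of these 10 genes, 9, all but TAF5L, did not pass without control replicate 2 (adjusted p from 0.0526 to 0.0749). Of the 20 arrays, left out 1 at a time, 17 ended the call of DNAH5, 16 that of CEBPA, 16 that of POU3F3, 13 that of RDH10, 10 that of SLC6A9, 10 that of PRM3, 9 that of NEUROG3, 6 that of ARHGEF35 and 3 that of RBFOX2. Of the genes that passed, 42.9% were higher, but 53.2% with quantile normalization and 62.2% with normexp.

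Compared with let-7d alone, both precursors gave 371 changed genes, 221 higher and 150 lower (756 with the slide as a block). The dose of each precursor in the combined group was not stated. A lower dose of let-7d there cannot be told apart from an added effect of miR-30b. ANKRD1, a stress-responsive muscle gene, and SERTAD4 were not above background with let-7d and were at least 1.58-fold and 1.73-fold higher with both (adjusted p = 0.00105 and 0.000264; 0.0568 and 0.105 with normexp). SFXN2, LYSMD1 and ACVR1C followed, and CEBPA (-3.53 ± 0.66), TAF5L, PRM3, EYA4 (-2.07 ± 0.24) and ANO3 (at least 1.36-fold, adjusted p = 0.401 with normexp) were lower. A second probe of TAF5L lay at 0.59, against -2.85. Fitting the compared groups alone left 17 genes and ended 6 of these 10 calls, those of SERTAD4, SFXN2, LYSMD1, ACVR1C, CEBPA and PRM3 (adjusted p from 0.0604 to 0.119). The count was 193 without replicate 5 and 613 without replicate 4 of the combined group. The share of higher genes was 59.6%, and 72.5% with median scaling and 69.8% with normexp.

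Compared with miR-30b alone, both precursors gave 67 changed genes, 23 higher and 44 lower (137 with the slide as a block, 2 when the compared groups were fitted alone). Here too, a lower dose of miR-30b in the combined group cannot be told apart from an added effect of let-7d. HMGA2 (-2.52 ± 0.11) and IGF2BP1 (-1.83 ± 0.18) were lower, as were TAF5L, the potassium channel subunit KCNE3 (at least 1.35-fold; adjusted p = 0.068 with quantile normalization, 0.0744 in the deposited table and 0.287 with normexp) and E2F5 (-1.36 ± 0.25). CSF2 (1.80 ± 0.37), ESM1 (1.40 ± 0.25), RND2, E2F7 and KRTAP1-1 were higher; CSF2 was above background on 1 of 5 miR-30b arrays, and its call ended with normexp (adjusted p = 0.145) and with no filter on dim probes (0.055). Fitting the compared groups alone ended 8 of these 10 calls, all but those of HMGA2 and IGF2BP1 (adjusted p from 0.0642 to 0.331). Single arrays left out ended the calls of CSF2 (7 of 20 arrays), KCNE3 (5), TAF5L (4), E2F5 (3) and ESM1 (1). Second probes lay at 0.14 for HMGA2, -0.09 for IGF2BP1, -0.60 for TAF5L and 0.67 for ESM1. The count was 21 without miR-30b replicate 4 and 21 without replicate 2 of the combined group.

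let-7d and miR-30b differed directly in 2645 genes, 1163 higher and 1482 lower with let-7d (3619 with the slide as a block). HMGA2 (-3.01 ± 0.11), SERTAD4 (at least 3.68-fold), IGF2BP1 (-2.63 ± 0.18), ANKRD1 (at least 2.04-fold) and E2F2 (-2.41 ± 0.25) were lower with let-7d. SOX8 (4.70 ± 0.81), NEUROG1, CEBPA, the sodium channel gene SCN3A (at least 3.41-fold) and CSF2 (3.12 ± 0.37) were higher with let-7d. The size for CSF2 is uncertain, since most miR-30b arrays had it at background. Second probes of HMGA2, IGF2BP1, E2F2 and SOX8 lay at 0.19, -0.18, -0.10 and 0.33. SOX8, NEUROG1 and CEBPA belong to the co-varying set. With median scaling, 770 genes were higher and 1592 lower with let-7d.

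The single effects were also compared across genes. The log2 fold changes of let-7d and miR-30b correlated at r = 0.550 over 12993 genes, which are not independent replicates. Unchanged groups simulated against the shared controls gave a mean r of 0.487 (from -0.749 to 0.961 in 100 simulations), and splitting the controls between the comparisons gave 0.480 (0.367 to 0.588 over 20 splits). The covariance was 0.141 against 0.0339 in the simulations, which reached 0.158. Both single precursors raised 372 genes and lowered 371, where independent lists would share 154 and 119, and 62 genes moved in opposite directions, against 274. Simulated unchanged groups, which hold no effects, shared 0 calls, and the counts for independent lists leave out the shared controls, so neither gives the overlap to expect without a shared effect. The combined effect regressed on the sum of the single effects with a slope of 0.472 (r = 0.874), against 0.330 and 0.541 in the simulations and 0.420 and 0.773 with split controls. The simulations ranged from -0.233 to 0.953 for the slope and from -0.342 to 0.980 for r, so both observed values lay inside those ranges. With array brightness as a covariate the correlation of the single effects was 0.348.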

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

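The tests of the co-varying genes, the spike-in test of the low region and all splits of the arrays were chosen after the result was seen; the test on all control spots and both tests of the genes low on slide 1 were not.

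A value stood apart from the other 4 arrays of its group (Dixon's test for 5 values) in 38 of 464 sets tested, where chance gives about 23.2, and 18 of them lay on let-7d replicate 1 and 8 on replicate 3 of the combined group. let-7d replicate 1 was the dimmest array (log2 75th percentile 7.63, with 61.7% of probes well above background). On it the normalized log2 signal stood apart for genes that include ANGPTL4 (2.68), ASPH (2.11), CCN2 (2.73), E2F2 (-0.14), FN1 (6.16), MYB (-0.71), PAQR9 (-3.69), PODXL (4.01), RBFOX2 (0.0474), SNAP23 (-1.94), TLR6 (-6.91) and TWF1 (3.20). It did so too for the means of the endoplasmic reticulum stress genes (3.29), ribosomal proteins (7.39) and endothelial markers (-2.19). On replicate 3 of the combined group, spots of 1 probe varied most (median CV of replicated probes 13.9%). Apart there were ASB16 (1.43), CCN2 (-4.27), HTR2B (-6.70), PKIA (-2.41), PUDP (-2.33), RP2 (-3.75) and SCN3A (-3.43).

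Other arrays had few such values. Among the controls these were CCL13 on replicate 2 (-8.59), ESM1 (-4.60), SNAI1 (0.89) and the interferon response mean (-0.81) on replicate 1, EYA4 on replicate 5 (-4.52), and HTR2B (-2.10) and RP2 (0.76) on replicate 4. With miR-30b they were IGF2BP2 (1.91) and MYB (-1.74) on replicate 1 and the interferon response mean on replicate 5 (-0.93). SCN3A on let-7d replicate 5 (-5.61) and FN1 on replicate 1 of the combined group (6.43) complete them.

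The combined effect differed from the sum of the single effects, with the dose of each precursor in the combined group not stated, for 170 genes, with the largest interactions at 1.83 for SLC6A9, 1.47 for ARHGEF35, 1.34 for RDH10, 1.30 for RBFOX2 and 1.28 for DNAH5. The lowest were -3.85 for CEBPA, -3.77 for TAF5L, -3.13 for PRM3, -2.84 for POU3F3 and -2.82 for NEUROG3. Among the lists it differed for the cytokines (-0.63) and the ribosomal proteins (-0.45). The call of the ribosomal proteins ended with an estimated correlation, and their mean turned to 0.0752 with quantile normalization and 0.0880 with normexp. Probes without a gene name here, which enter the counts for every probe on its own but no comparison of genes, also changed: 1431 of 9973 with let-7d, 2026 with miR-30b and 1028 with both. These are 14.3%, 20.3% and 10.3%, against 16.0%, 23.1% and 13.7% of named probes.

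Of the 10 largest rises with let-7d among genes whose groups did not overlap, 8 belong to 192 genes (18.3% of the 1047 higher ones) that vary together between arrays of 1 group. The set was built from those 10 rises, as the genes higher with let-7d whose deviations within groups correlated above 0.8 with theirs, so this membership follows in part from the choice. With array brightness as a covariate their median rise went from 1.89 to 1.32, and 92 of them still passed. The lower quartile of their rises stayed at 0.96, and with miR-30b, the dimmer group on average, their median was 0.72. The genes were chosen for their rise with let-7d and vary together. These values therefore cannot decide whether brightness is the whole source. How much of the rise it makes cannot be told apart from the precursor, since the dimmest array is a let-7d array and the controls were the brightest group on average. Their deviations within groups were shared between arrays of 1 slide (permutation p = 0.0250), but each slide holds every group, so a slide effect cannot make the rise. Other probes of the same genes (69 probes of 55 genes) had a median of 0.20, where the probes used had 2.07; a candidate explanation is signal of single probes rather than of the genes, though the other probes are dimmer and the set was chosen for the rise of the probes used. An effect of let-7d on these genes stays open.

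On replicate 3 of the combined group, 579 of the 581 lowest gene spots lay in 1 round region. The 30 control spots inside it had a median difference of 0.68 from their copies elsewhere on that array, which decides nothing, since 19 of them have no signal elsewhere to lose. The 10 spike-in spots with signal elsewhere read lower inside (median -4.21, from -7.54 to -2.09), which is consistent with a local loss of signal on the array surface. The same RNA met all parts of the array, and no biological explanation was tested.

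On slide 1, 42 genes were low in all 4 groups, by a median of 2.43 below slides 2 to 4. The rule for these genes left slide 5 out. Slides 2 to 4 lay 1.80 above the mean of slides 1 and 5, more than slide 1 alone would give, so slide 5 was lower too. With a stricter rule, lower than on every other slide, 10 genes were found for slide 1 and 0 for each other slide. Residual genomic DNA on slides 2 to 4 may raise olfactory receptor genes, which are silent in fibroblasts. Their 114 probes had a median difference of -0.28 between slides 2 to 4 and the mean of slides 1 and 5, a measure on which the genes of the pattern had 1.80 and all probes -0.12. The test cannot exclude genomic DNA: slide 1 held the dimmest array of each group, where the scaling can raise dim probes, and olfactory genes need not stand for the genes of the pattern. With array brightness as a covariate the median difference of slide 1 from all other slides was 2.43, against 2.15 without. A difference from slides 2 to 4 had been planned. The value did not shrink, but slide 1 held the dimmest array of each group, so the fit cannot exclude brightness. A difference between the cultures or hybridizations that share a replicate number may remain as an explanation, and it was not tested. The design names no group that matches the slides, so no biological explanation was tested.

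Chance assignment of arrays to groups was tested with 100 splits each, the real one included, that move arrays freely between slides with no block. For 6 of the 7 comparisons the share of splits with as many genes was under 0.05, not adjusted over the comparisons. For let-7d, miR-30b and let-7d against miR-30b no other split reached the real count, which argues against free chance assignment, though not against a structure by slide. Where other splits exceeded the real count, chance is not excluded. For the interaction, arrays of all groups were exchanged, here and within slides, so its splits do not test for an interaction alone. For let-7d against control, 1 split gave as many genes (real count 2101, highest of the others 1). For miR-30b it was 1 (3383, highest other 1505), for both precursors 3 (2154 and 3172), for the interaction 2 (170 and 294), for both against miR-30b 3 (67 and 1163), and for let-7d against miR-30b 1 (2645 and 1786). For both against let-7d, 6 of 100 splits gave as many genes as the real one (371 and 3635), so free chance assignment cannot be excluded there either. Splits that call several times the real count point to a structure of the samples. The highest one for both against let-7d set apart let-7d replicate 1 with replicates 1, 2, 3 and 5 of the combined group, and that for both against miR-30b set apart miR-30b replicates 1, 3 and 5 with replicates 4 and 5 of the combined group. With the slide as a block and arrays exchanged only within slides, the 16 splits of 2 groups are too few for a share under 0.05: the real and the highest other count were 3182 and 0 for let-7d, 4180 and 0 for miR-30b, 2869 and 3831 for both, 756 and 0 for both against let-7d, 137 and 656 for both against miR-30b, and 3619 and 1399 for let-7d against miR-30b. For both and for both against miR-30b, 2 of the 16 splits gave as many genes, the real one included, so these 2 counts are no larger than slide-wise exchange can give. For the interaction, 3 of 100 such splits gave as many genes (341 and 5518).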

How the results depend on the processing

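Array brightness as a covariate, with and without the replicate block, the low region left out, every probe on its own and the fit without the dimmest array and the array with the low region were chosen after seeing the data; all other alternatives were fixed before. Counts are for let-7d, miR-30b and both precursors against control, for the interaction, and for both against let-7d, both against miR-30b and let-7d against miR-30b; unless a reason is given, the cause was not tested.

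Array brightness as a covariate gave a correlation of the single effects of 0.348, 5 lists for both precursors, and 439 interaction genes, 5083 for let-7d against miR-30b, 1392 for both against let-7d and 408 for both against miR-30b. Median scaling gave 51 interaction genes and 25 for both against miR-30b. With no filter on dim probes, which adds genes to the adjustment, the interaction had 85 genes and 4 lists and both against miR-30b 30 genes. Fitting only the groups compared, with fewer arrays behind the spread, gave 17 genes for both against let-7d, 2 for both against miR-30b and 5242 for miR-30b. A minimum of 1.5-fold, stricter by construction, left 1385 genes for let-7d, 2100 for miR-30b, 1307 for both and 1587 for let-7d against miR-30b. Every probe on its own, with more probes than genes, gave 4437 for let-7d, 6378 for miR-30b, 3612 for both, 259 for the interaction, 611 for both against let-7d and 4719 for let-7d against miR-30b. Camera with an estimated correlation kept 2 lists for let-7d, 1 for miR-30b, 4 for both and 1 for the interaction, and fry called 7 for miR-30b and 1 for the interaction. Without the dimmest array and the array with the low region there were 7 lists for let-7d, 375 interaction genes and 208 genes for both against miR-30b.

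With the replicate block the counts were 3182 for let-7d, 341 for the interaction, 756 for both against let-7d and 137 for both against miR-30b, and within 1.5 times the count without it for the other comparisons. The block together with brightness gave a correlation of 0.355, 7 lists for let-7d and 5 for both, 317 interaction genes, 5894 for let-7d against miR-30b, 2569 for both against let-7d and 896 for both against miR-30b. Deviations of arrays with the same number correlated above 0.1 in 23 of 30 pairs (from -0.17 to 0.70), among them all 5 pairs of control with let-7d (0.36 to 0.52) and all 5 of control with miR-30b (0.23 to 0.60). Not every array correlated best with its own number. The number marks a shared slide, which the block takes up, and beyond that it was not taken to pair the cultures.

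Among results that passed with the main values, directions turned for few. CCN1 with miR-30b was -0.0752 with normexp, -0.0621 with quantile normalization and -0.0114 in the deposited table, against 0.35. The ribosomal proteins turned with normexp and with quantile normalization: -0.16 and -0.16 for let-7d, -0.0297 and -0.0386 for miR-30b, -0.10 and -0.12 for both, and 0.0880 and 0.0752 for the interaction. Other matrix genes with let-7d had a mean of 0.01 with the block and brightness. Over named genes, 13542 values under the alternatives stayed on their side of the threshold, 1075 no longer passed and 213 newly passed. Over the lists these were 2729, 138 and 59. Values that passed neither with the main values nor under the alternative count as unchanged here, whatever their direction.

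Without single arrays, let-7d gave 1270 to 2606 genes and 5 to 12 lists, miR-30b 2300 to 3704 and 4 to 6, both 1294 to 4226 and 6 to 9, the interaction 42 to 359 and 2 to 4. Both against let-7d gave 193 to 613, both against miR-30b 21 to 92 and let-7d against miR-30b 1824 to 3012, the correlation of the single effects 0.478 to 0.586 and the slope on their sum 0.404 to 0.563. Arrays that moved a count by over 1.5 times were, for let-7d, control 3 (1270) and 5 (1282), and for both, control 2 (1319), 3 (1301) and 5 (1391) and combined 3 (1294) and 4 (4226). For both against let-7d they were let-7d 1 (597), 2 (216), 3 (200) and 4 (245) and combined 4 (613) and 5 (193), and for both against miR-30b, miR-30b 2 (30), 4 (21) and 5 (22) and combined 1 (33) and 2 (21). For the interaction they were control 1 (87), 2 (42), 3 (58) and 5 (56), let-7d 2 (59), 3 (90) and 4 (65), miR-30b 1 (256), 2 (63), 3 (105), 4 (52) and 5 (57), and combined 2 (93), 3 (359) and 4 (98). For lists, the interaction had 4 without combined 1, and let-7d 7 without control 1 and 5 without let-7d 2.

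Signal over background limits the dim genes: 17042 of 41000 probes had no name, and dim probes have only bounds where a group lies at background. In simulated data with independent noise the 5 arrays per group found 14.9% of interactions of 1.5-fold and 92.4% of those of 4-fold. The 6 planned results on seed matches in 3' untranslated regions, with their alternatives, were not run, because the sequences were not part of the reference used here.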

Other observations

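The tests of the symbol families and of competition were chosen after the result was seen; the lists were fixed before the data were examined.

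Enzymes that modify the matrix went both ways and did not pass as a list with let-7d (5 higher and 5 lower of 29, camera adjusted p = 0.959), miR-30b (4 and 4, 0.759) or both (4 and 4, 0.393). PLAU, the urokinase that activates plasminogen, rose with let-7d (0.95 ± 0.16) and miR-30b (0.99 ± 0.16), and the collagenase MMP1 rose with let-7d (1.06 ± 0.26), miR-30b (0.88) and both (0.98). Contractile genes did not pass (3 higher and 4 lower of 21 with miR-30b, adjusted p = 0.759; 1 and 1 with both, 0.393), with TPM1 up by 0.65 and FLNA, filamin A, at -0.93 with miR-30b. Mesenchymal transition factors did not pass (adjusted p = 0.14, 0.978 and 0.393 for let-7d, miR-30b and both), although ZEB2, a repressor of epithelial genes, rose in all 3 (0.95, 0.43 and 0.72). Interferon response genes did not pass (0.271, 0.759 and 0.357), with EPSTI1 at -1.06 with miR-30b and STAT2 at -0.82 with let-7d. Genes of cholesterol synthesis did not pass (0.117, 0.835 and 0.297), with 6 higher and 4 lower of 24 for miR-30b, among them SQLE (0.95). Hypoxia and glycolysis genes did not pass (0.318, 0.759 and 0.681), while hexokinase HK2 rose with miR-30b and with both (0.82 and 1.18).

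Autophagy genes did not pass with let-7d, miR-30b or both (adjusted p = 0.271, 0.978 and 0.393), although 7 of 28 rose with miR-30b, ULK2 by 0.87, and 2 fell, BECN1 by 0.44. Genes of endoplasmic reticulum and amino acid stress did not pass (0.0992, 0.978 and 0.677), with the chaperone HSPA5 lower in all 3 (-0.68, -0.69 and -0.72). G1/S genes (0.959), G2/M genes (0.914) and p53 targets (0.271) did not pass with let-7d, where the phosphatase CDC25B fell by 1.09; with miR-30b, p53 targets (0.21), respiratory chain genes (0.234), RAS feedback genes (0.21) and small RNA genes (0.759) did not pass, nor did respiratory chain (0.0878) and small RNA genes (0.376) with both. Markers of other cells did not pass in the remaining comparisons: epithelial 0.207, 0.978 and 0.393, pericyte and smooth muscle 0.437, 0.766 and 0.681, and for miR-30b and both endothelial 0.978 and 0.67 and erythroid 0.759 and 0.269. Mesothelial markers had 3 measured members and were not tested; CALB2 fell with miR-30b by 1.18. Among 143 families of genes whose symbols start alike, each with at least 10 members, 9 passed with let-7d, 5 with miR-30b, 6 with both and 6 for the interaction, and none of them with an estimated correlation. With let-7d, 6 of 14 KRTAP genes, of hair keratin partners, rose (mean 0.95, adjusted p = 0.00282; adjusted p = 0.847 with an estimated correlation and 0.0213 with brightness). Of those that rose, KRTAP1-3, KRTAP2-4 and KRTAP4-1 belong to the co-varying set. Among GALNT genes, which start O-linked sugar chains, 5 of 14 fell with miR-30b (mean -0.36, adjusted p = 0.048; adjusted p = 0.72 with an estimated correlation and 0.667 with array brightness as a covariate). LSM genes of RNA processing rose in 8 of 13 cases with miR-30b (adjusted p = 0.0261; adjusted p = 0.977 with an estimated correlation and 0.667 with brightness).

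A transfected precursor may compete with the cells' own microRNAs for the silencing complex, which would raise targets of the other microRNA. With miR-30b, 12 of 37 let-7 targets rose and 1 fell, with a mean of 0.23 and a median of 0.07, but the list did not lie above the other genes at the threshold (camera adjusted p = 0.21). With let-7d, miR-30 targets had 2 members higher and 4 lower and a mean of -0.11 (camera adjusted p = 0.271). Neither test decides for or against competition, since these p-values do not show that the lists stayed unchanged and some let-7 targets that rose are also cell cycle genes.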
